A study of Mus musculus with 3 samples.

How the data were processed

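Single-nucleus multiome libraries (RNA and ATAC from the same nuclei) had been made from wild-type mouse hearts. The titles carry 3 months, whose meaning (age or treatment time) is not stated. Groups were taken from the sample titles and the study design text: vehicle, sunitinib (titled with the drug class) and sunitinib plus Yoda1 (titled with Yoda1 only), with 1 library each. Only the ATAC fragment files were used, and the RNA arm was not analysed here. Per the file headers, the authors made the fragments with cellranger-arc against mm10, version 2.0.0 for the vehicle and sunitinib libraries and 2.0.2 for the sunitinib plus Yoda1 library, so the version differs together with the group. The deposited values are a count of read pairs behind each unique fragment of each barcode, with nothing normalized and all barcodes kept. The authors name Cell Ranger and Signac as tools, and no deposited nucleus calls, clusters or peaks were used here.

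A barcode was called a nucleus with at least 1000 unique fragments on the autosomes and X, an enrichment of at least 4 at transcription start sites (fragment ends within 50 bp over those at 1900 to 2000 bp) and a ratio of fragments of 147 to 294 bp over shorter fragments under 4. No doublet caller was run and doublets were not removed. Called barcodes held up to 64499 fragments under vehicle and 97791 under sunitinib. For cardiomyocyte-like nuclei the lists, summed markers and some named genes are also given without the 5% of nuclei with most fragments. Genes came from the GENCODE annotation of mm10 (21728 protein-coding genes). Called nuclei of the 3 libraries were clustered together by latent semantic indexing of 60000 genome tiles of 5 kb (30 components, 20 neighbours) and Leiden clustering at resolution 0.8. Clusters were named from markers of 12 cell classes, where at least 3 markers had to be at least 2-fold more accessible than in the other nuclei. Names end in -like because no other evidence of identity was used.

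Fragments over each gene body plus 2 kb upstream were summed per class and library and divided by the fragments of the same nuclei. Log2 ratios had 0.5 counts added to each side, with conditional exact 95% intervals. Shares have exact Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 counts set. A gene was measured with at least 200 fragments over both libraries and an expected 30 in each. Named genes were the 12 highest and 12 lowest autosomal protein-coding genes in cardiomyocyte-like nuclei whose direction was the same within 1 kb of the transcription start sites, then Piezo1, 9 kinases blocked by sunitinib, and the 3 leading members of each gene list that lay in the outer 2.5%. A few of the genes that met these rules are not reported here. The medians of 27 gene lists, over members with at least 50 fragments, were placed among 10000 random lists matched in 20 bins of accessibility. This places a list within these libraries and is no test between groups. The groups, the lists, the markers, the thresholds above, the rule for named genes and most alternatives were fixed before the data were examined.

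Other choices were made after the data were seen. Of the fragments in the sunitinib plus Yoda1 library, 42.1% shared their start and end with another barcode, against 0.202% and 0.213% in equal numbers of vehicle and sunitinib fragments. Fragments with at least 100 read pairs (258020, or 44.3%) shared them in 0.288%, so whole-library comparisons with this library used these fragments. The comparison of a chromosome segment in the last part used all fragments instead. The vehicle and sunitinib values came from 581823 fragments each, and sharing rises with the number of fragments. The 0.288% is therefore not on the same base, and some excess of shared positions may remain. The cutoff was chosen after several had been viewed. Whole-library comparisons, with the same rule for named genes, were themselves added because 12 nuclei were too few. The class without nuclei of low quality is the cardiomyocyte-like cluster at resolution 1.5. The genes of 4 T cell and thymus lists (immature thymocytes, mature T cells, all T cells, thymic epithelium) were written after the leading genes of the T-like cluster had been seen.

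The correlation between comparisons that share a library was set beside 200 simulated sets of libraries without differences. On data simulated from the depths of the cardiomyocyte-like nuclei (2454 genes), 96.7% of intervals held the true ratio, 24 of 24 named genes were truly changed, intervals excluded 0 for 87% of genes changed 1.5-fold and 100% changed 2-fold, and 3.22% of unchanged genes had an interval that excluded 0. Of 100 random lists without change, 3 lay in the outer 5%. These simulated counts held counting error only, which is also what the intervals assume. Their named genes were picked by ratio alone, without the condition on transcription start sites. The simulation therefore checks the computation and cannot show how the intervals or the rule for named genes hold under variation between nuclei or animals. Alternatives to each choice are given in the closing section. No accessible motifs were analysed, since no genome sequence was held. No paired analysis was possible because each group had a single library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.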

Results

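Nuclei from wild-type mouse hearts were profiled by single-nucleus multiome sequencing. The chromatin accessibility arm (ATAC) was used and the RNA arm was not analysed here. The hearts had been given vehicle, sunitinib (an inhibitor of receptor tyrosine kinases used against tumours) or sunitinib together with Yoda1 (a chemical activator of the stretch-gated cation channel PIEZO1), with 1 library per group. There were no replicates, so no difference could be set against the variation between animals, and all 95% intervals cover counting error only. The vehicle library held 18704581 unique fragments from 148947808 read pairs, the sunitinib library 23653823 from 210143978, and the sunitinib plus Yoda1 library 583792 from 209296546. Barcodes that met the criteria for a nucleus numbered 2690, 3861 and 12 in that order, with medians of 2160, 2371 and 1326 fragments per nucleus. Cell classes were therefore compared between vehicle and sunitinib, and the sunitinib plus Yoda1 library was compared as a whole, with its 258020 fragments backed by at least 100 read pairs.

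**Figure D1:**
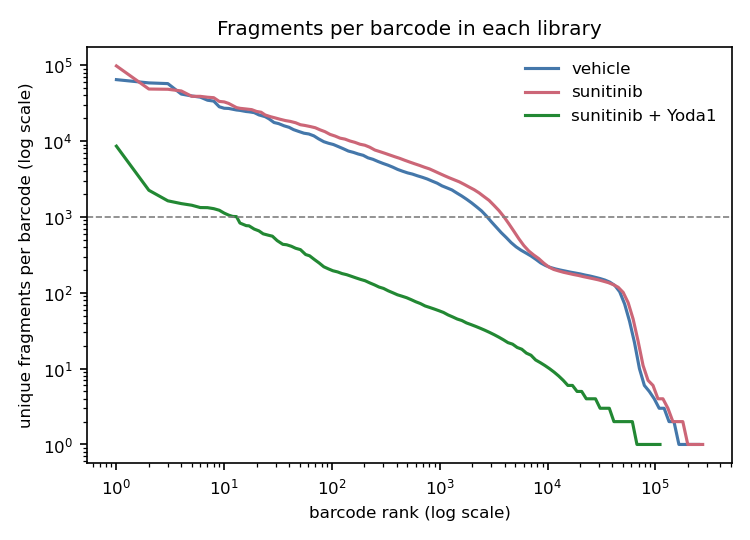
Unique fragments per barcode (log axis) against the rank of the barcode (log axis) for the 3 libraries, with the minimum of 1000 fragments per nucleus drawn as a line. The sunitinib plus Yoda1 curve lies below the other curves, and 12 of its barcodes were called as nuclei against 2690 and 3861.

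The first comparison, sunitinib against vehicle, asks which cells and which chromatin differed in the heart under the kinase inhibitor. Nuclei with accessible T lymphocyte genes made up 1443 of 3861 nuclei of the sunitinib library (37.4%, exact Clopper-Pearson interval 35.8 to 38.9) and 264 of 2690 of the vehicle library (9.81%, 8.72 to 11). Over the whole libraries the highest log2 ratios were accordingly at Cd3e and Cd3d, which encode chains of the T cell receptor complex (1.61, interval 1.36 to 1.87, and 1.35, 1.13 to 1.57), at the co-receptor genes Cd8b1 (1.32, 1.13 to 1.52) and Cd8a (1.23, 0.92 to 1.55), and at Rag1, the recombinase that assembles antigen receptor genes (1.26, 0.99 to 1.54). Vascular endothelial-like nuclei took 28.1% under sunitinib and 39.0% under vehicle, fibroblast-like nuclei 7.80% and 14.2%, endocardial-like nuclei 1.71% and 6.10%, and epicardial or mesothelial-like nuclei 0.466% and 1.60%. Cardiomyocyte-like nuclei took 14.8% and 14.5%, myeloid-like nuclei 3.73% and 6.73%, mural-like nuclei (pericytes and smooth muscle) 3.6% and 5.06%, and B lymphocyte-like nuclei 2.46% and 2.97%. Among nuclei outside the lymphoid classes, cardiomyocyte-like nuclei were 24.5% of the sunitinib library (22.8 to 26.3) and 16.7% of the vehicle library (15.2 to 18.2). On the same base endocardial-like nuclei were 2.84% (2.20 to 3.6) and 6.99% (5.99 to 8.10), fibroblast-like nuclei 13% and 16.2%, and endothelial-like nuclei 46.7% and 44.8%. Shares of nuclei can be set by the preparation, and with at least 3000 fragments required the T-like shares were 27.1% and 5.34%. Among nuclei outside the lymphoid classes that requirement gave cardiomyocyte-like shares of 14.8% (12.7 to 17.1) and 11.8% (9.61 to 14.3), endocardial-like 4.22% and 12.2%, fibroblast-like 18.3% and 18.1%, and endothelial-like 47.2% and 39.1%.

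**Figure D2:**
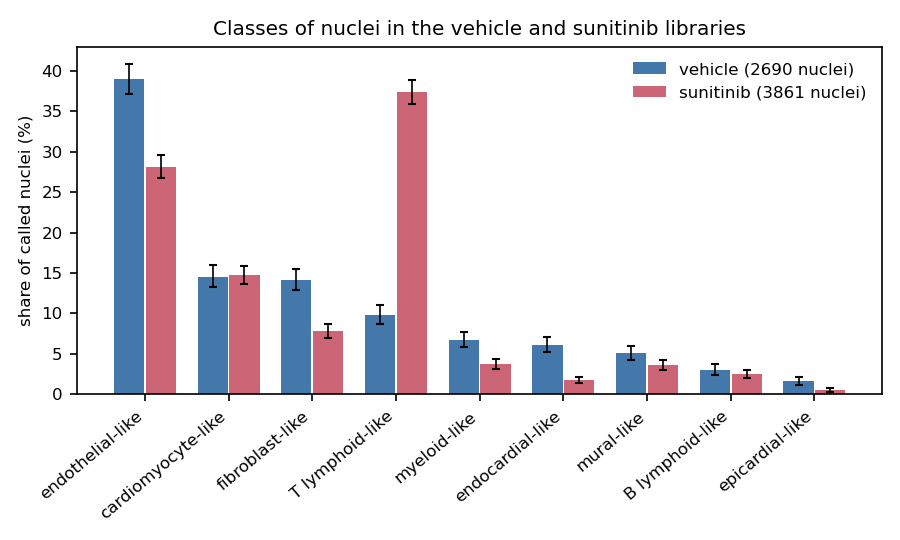
Share of called nuclei (percent) per cell class in the vehicle and sunitinib libraries, with exact 95% intervals for counting error. T lymphocyte-like nuclei stand at 9.81% under vehicle and 37.4% under sunitinib, while cardiomyocyte-like nuclei stand at 14.5% and 14.8%.

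Among the lowest whole-library ratios Ankrd1, a stretch- and stress-responsive muscle gene, stood at -0.89 (-1.25 to -0.54), Tcf21, a transcription factor of cardiac fibroblasts, at -0.81 (-1.20 to -0.42), and Tmem119 at -0.77 (-1.07 to -0.48). The median of all 15466 measured genes was 0.10. Of 27 gene lists, 4 lay in the lowest 2.5% of matched random lists and 1 in the highest 2.5%: extracellular matrix genes (median -0.18, 14 of 15 members lower), targets of the stretch-responsive YAP and TEAD factors (-0.16, 12 of 14 lower), the kinases that sunitinib blocks (-0.14, 7 of 9 lower, but Flt3 at 0.67, 0.53 to 0.82) and sarcomere genes (-0.09, 12 of 18 lower), against cell cycle genes (0.24, 18 of 20 higher). The larger share of T-like nuclei in the sunitinib library can shift these ratios. How far it did so is not given here for the single genes. When nuclei of the lymphoid classes were left out, 2 lists lay in the lowest 2.5% and 1 in the highest, which was not that of cell cycle genes. Within 1 kb of transcription start sites 8 lay in the lowest 2.5% and 0 in the highest. With random lists matched also on length these numbers were 6 and 0. Cell cycle genes also left the highest 2.5% with fragments shorter than a nucleosome and with 1 fragment per start and end.

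Within cardiomyocyte-like nuclei the gene of the mitochondrial master regulator PGC-1alpha was less accessible under sunitinib. Ppargc1a (chromosome 5, 51454250 to 51567726, mm10) carried 269 fragments in the sunitinib library and 309 in the vehicle library, or 132.5 and 267.5 per 1000000, a log2 ratio of -1.01 (-1.25 to -0.77). Flnc, which encodes the Z-disc crosslinker filamin C (chromosome 6, 29433256 to 29461883), stood at -1.10 (-1.44 to -0.77). The lowest ratio was at Cmtm5 (chromosome 14, 54936261 to 54939274), which lies beside the cardiac myosin genes Myh6 and Myh7, at -1.35 (-1.75 to -0.95). Csrp3, the Z-disc protein MLP whose loss causes cardiomyopathy, stood at -0.76 (-1.15 to -0.37), Adcy6, a main adenylyl cyclase of the beta-adrenergic response, at -0.79 (-1.19 to -0.38), and Mylk4, a myosin light chain kinase of the heart, at -0.75 (-1.10 to -0.39). The zinc and iron transporter gene Slc39a14 (-0.79), the Wnt co-activator gene Bcl9 (-0.95), Kctd8 (-0.91), Rilpl1 (-0.74), Mafk (-0.73) and Rfx4 (-0.73) completed the 12 lowest. The median of the 2485 measured genes was -0.06. Relative to the summed cardiomyocyte markers of whole libraries, Cmtm5 (-0.62), Flnc (-0.56), Ppargc1a (-0.61) and Kctd8 (-0.75) were also lower under sunitinib. The intervals of Csrp3 (-0.03), Mylk4 (-0.11), Adcy6 (-0.07), Slc39a14 (-0.04), Mafk (0.04) and Rfx4 (-0.04) included 0 there. Bcl9 (0.12) and Rilpl1 (0.14) were higher. Whole libraries also hold the other cell classes.

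Nuclei of low quality gave 51.0% of the fragments of the cardiomyocyte-like class under sunitinib and 35.3% under vehicle, while they were 31.1% and 29.4% of its nuclei. Of them 22 and 6 held over 10000 fragments. The summed cardiomyocyte markers of the class stood at a log2 ratio of -0.34 to vehicle (-0.40 to -0.27). With these 177 nuclei left out under sunitinib and 115 under vehicle, whose median enrichment at transcription start sites was 8.67 and 8.40, that ratio was -0.05 (-0.12 to 0.01). Ppargc1a then stood at -0.86 (-1.13 to -0.60), Flnc at -0.96 (-1.33 to -0.60), Cmtm5 at -1.08 (-1.51 to -0.67) and Csrp3 at -0.48 (-0.88 to -0.07). Relative to the summed cardiomyocyte markers Ppargc1a stood at -0.68 (-0.92 to -0.44) with all nuclei of the class and at -0.81 (-1.08 to -0.55) without those of low quality. Without the 5% of nuclei with most fragments the summed markers stood at -0.07 (-0.14 to -0.0045), Cmtm5 at -0.996, Flnc at -0.83, Ppargc1a at -0.71, Adcy6 at -0.46, Slc39a14 at -0.37 and Csrp3 at -0.35. Ppargc1a and Cmtm5 were among the 10 genes that best set the class apart, so the class and these ratios are not independent.

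The highest ratios in cardiomyocyte-like nuclei were smaller in size. Septin gene Sept10 (chromosome 10, 59141627 to 59221847) led with 1.05 (0.57 to 1.57), and it was also higher in barcodes with under 500 fragments (0.66), which were not called as nuclei. Next came the neuronal adhesion genes Cntnap5c (0.75, 0.40 to 1.11) and Cntnap5b (0.65, 0.32 to 1.00), Pcbp3 (0.74), Plekha2 (0.72), the basement membrane collagen gene Col15a1 (0.69, 0.28 to 1.13), Clip2 (0.66), Map2 (0.63), Setd3 (0.62), the adaptor gene Nck2 (0.62), Eml4 (0.61) and Cmah (0.60). Without the 5% of nuclei with most fragments Cntnap5b stood at 0.37, Col15a1 at 0.32 and Map2 at 0.09. Over all called nuclei Cntnap5b stood at -0.11 and Map2 at -0.003.

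**Figure D3:**
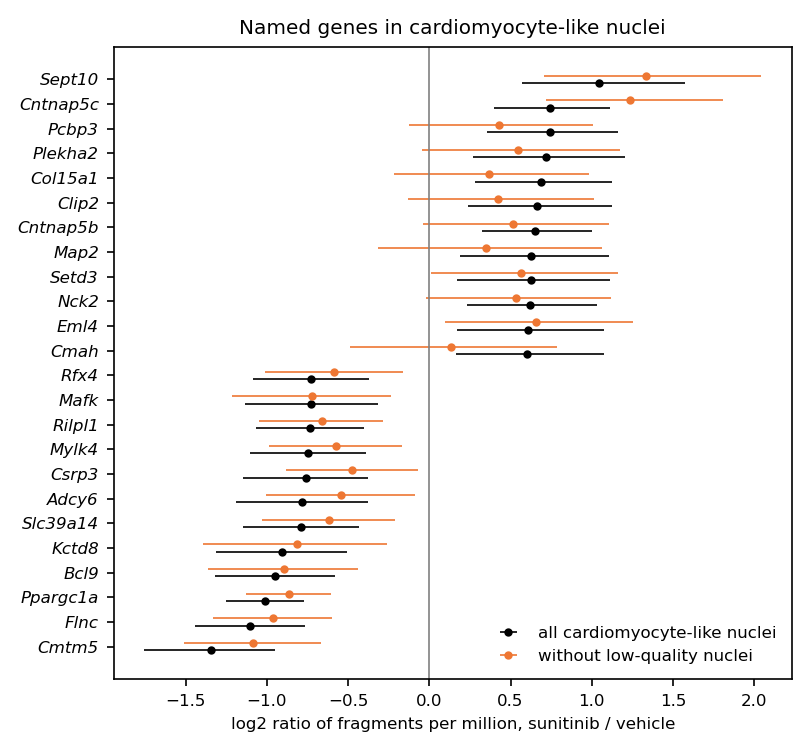
Log2 ratio of normalised fragment counts, sunitinib over vehicle, in cardiomyocyte-like nuclei for the 12 lowest and 12 highest genes, with all nuclei of the class (black) and without those of low quality (orange), each with its 95% counting interval. Cmtm5, Flnc and Ppargc1a lie at -1.35, -1.10 and -1.01 with all nuclei and at -1.08, -0.96 and -0.86 without those of low quality.

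Lists of heart muscle genes lay low together in these nuclei. The fetal and stress programme was lowest, with a median of -0.61 and all 9 measured members lower, among them Myh7, the slow myosin heavy chain (-0.67, -0.97 to -0.38), Nrap (-0.62, -0.87 to -0.38) and Xirp2 (-0.61, -0.99 to -0.22). Cardiac ion channels had a median of -0.35 (12 of 14 lower), with the transient outward potassium channel genes Kcnd3 (-0.58, -0.83 to -0.34) and Kcnd2 (-0.40, -0.68 to -0.11). Calcium handling genes had a median of -0.31 (13 of 13 lower), with calsequestrin Casq2 (-0.57), the sodium-calcium exchanger Slc8a1 (-0.50) and junctophilin Jph2 (-0.48). Sarcomere genes had a median of -0.28 (17 of 18 lower), with Csrp3, Actn2 (-0.55) and titin, Ttn (-0.52, -0.62 to -0.41). The medians of ion channel, calcium handling and sarcomere genes were similar to the lower summed cardiomyocyte markers of the class given above. No list was set relative to those markers. Myh7 and Ttn were among the 10 genes that best set the class apart. Ttn and Actn2 were among the markers that named it, so the class and these ratios are not independent.

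Metabolic lists were also in the lowest 2.5% of matched random lists. Fatty acid oxidation had a median of -0.34 (13 of 18 lower), with Hadhb of the trifunctional protein (-0.69, -1.07 to -0.31), the fatty acid transporter Cd36 (-0.52, -0.80 to -0.24) and Pdk4 (-0.43). Glycolysis and glucose uptake had -0.30 (15 of 17 lower; Pkm -0.36, Irs1 -0.30, Hk1 -0.04), AMPK energy sensing -0.29 (12 of 14 lower; the catalytic subunit Prkaa2 -0.61, Fnip1 -0.39, Acacb -0.34), and lipid and cholesterol genes -0.29 (10 of 15 lower; Dgat2 -0.50, Abca1 -0.13). Autophagy and lysosome genes had -0.33 (11 of 13 lower; Wipi1 -0.60, Tfeb -0.37, Atg7 -0.29), glucocorticoid and FOXO targets -0.30 (10 of 13 lower; Zbtb16 -0.49, Per1 -0.36), and YAP and TEAD targets -0.26 (11 of 13 lower; Tead1 -0.30, Amotl2 -0.26, Arhgef17 -0.15). Stretch-gated and related channels were the 1 list in the highest 2.5% (median 0.19, 9 of 14 higher), with Piezo2 at 0.53 (0.15 to 0.93). This list had a median of 0.17 both without nuclei of low quality and without the 5% of nuclei with most fragments, inside the range of 95% of random lists. Piezo2 without nuclei of low quality stood at 0.33 (-0.19 to 0.86). In total 11 of 27 lists were in the lowest 2.5%. The other 15 lay between, among them oxidative phosphorylation (-0.14), mitochondrial biogenesis (-0.22) and hypoxia genes (-0.13). Without the nuclei of low quality 2 lists stayed in the lowest 2.5%, the fetal and stress programme (-0.39) and cardiac ion channels (-0.30), while sarcomere genes stood at -0.02. Within 1 kb of transcription start sites no list did, of 19 measured, and without the 5% of nuclei with most fragments 1 list did, autophagy and lysosome genes (-0.29).

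**Figure D4:**
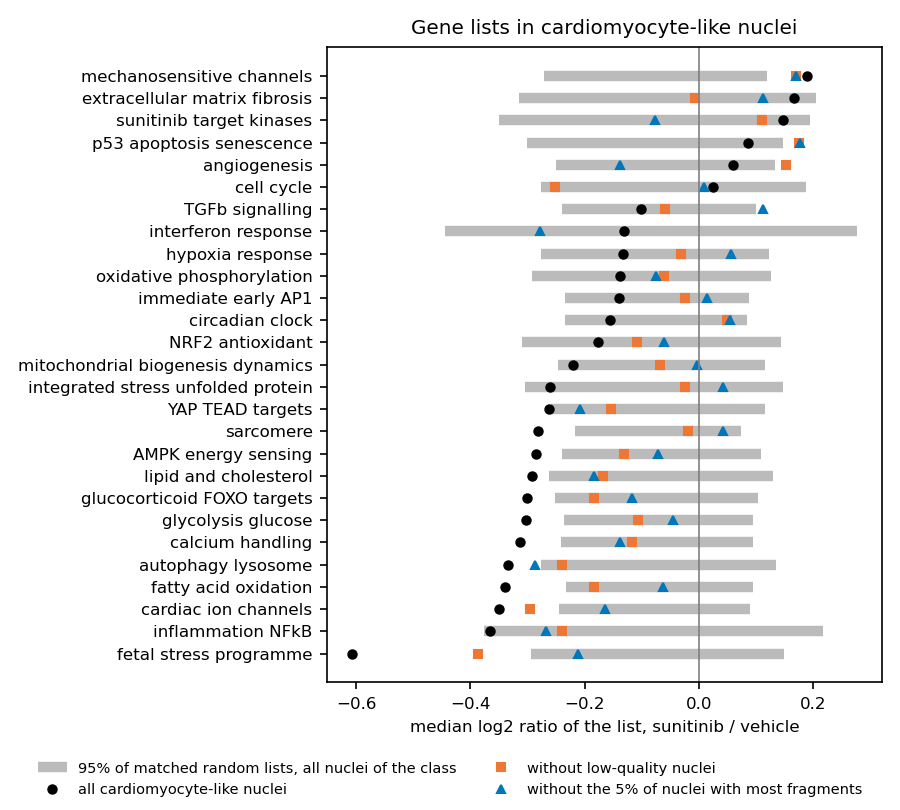
Median log2 ratio, sunitinib over vehicle, of the 27 gene lists in cardiomyocyte-like nuclei, with all nuclei (black circles), without nuclei of low quality (orange squares) and without the 5% of nuclei with most fragments (blue triangles), over the range of 95% of random lists matched to the first (grey bars). The fetal and stress programme lies at -0.61, -0.39 and -0.21, and stretch-gated channels lie highest with all nuclei at 0.19.

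Piezo1, the target of Yoda1, and the receptor kinases blocked by sunitinib were read in each class whatever their ratio. In cardiomyocyte-like nuclei Piezo1 (chromosome 8, 122481698 to 122551329) carried 169 fragments under sunitinib and 75 under vehicle, a log2 ratio of 0.35 (-0.04 to 0.77), with -0.31 within 1 kb of its transcription start sites and 0.58 (0.02 to 1.19; 78 and 39 fragments) without nuclei of low quality. In vascular endothelial-like nuclei Piezo1 stood at 0.17 (0.01 to 0.32), in fibroblast-like nuclei at 0.10 (-0.25 to 0.46), and over the whole libraries at -0.02 (-0.10 to 0.06). Kdr, the main VEGF receptor and a sunitinib target, was higher in vascular endothelial-like nuclei (0.24, 0.10 to 0.39) and in endocardial-like nuclei (1.03, 0.51 to 1.55), whereas Flt1, the decoy VEGF receptor, stood at -0.01 in endothelial-like nuclei (-0.12 to 0.09). Flt4, the lymphatic VEGF receptor, stood at 0.86 (0.10 to 1.60) in endocardial-like nuclei. Flt4 was among the lymphatic endothelial markers, whose median log2 ratio over the other nuclei was 0.78 in the endocardial-like cluster. Lymphatic cells were not separated from that class. The pericyte receptor gene Pdgfrb was lower in mural-like nuclei (-0.40, -0.79 to -0.02), and Csf1r, the macrophage growth factor receptor, was higher in myeloid-like nuclei (0.52, 0.04 to 1.01) and lower in vascular endothelial-like (-1.06, -1.82 to -0.34; 27 and 42 fragments) and fibroblast-like nuclei (-1.85, -3.54 to -0.55; 6 and 19 fragments). Ret was lower in vascular endothelial-like nuclei (-0.54, -0.98 to -0.11). Flt3 had 3 fragments and 0 in epicardial-like nuclei. These were the 10 of 90 values, of 10 genes in 9 classes, with intervals that excluded 0. Outside Piezo1, Kdr and Pdgfrb in endothelial- and mural-like nuclei they rest on fewer fragments than the minimum for a measured gene. In the simulation 3.22% of unchanged genes had an interval that excluded 0, so some of the 10 can arise from counting error alone. Kdr and Flt1 were among the markers that named the vascular endothelial-like class, Pdgfrb the mural-like and Csf1r the myeloid-like class. In those classes the class and these ratios are not independent. In cardiomyocyte-like nuclei the intervals of all 9 kinases included 0, with Kit at 0.32 and Csf1r at -0.61 as the extremes.

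In the other classes the lists that stood apart between sunitinib and vehicle depended on the processing. With all nuclei, TGF-beta signalling genes were in the highest 2.5% in vascular endothelial-like nuclei (median 0.15, 10 of 15 higher), and extracellular matrix genes were in the lowest 2.5% in fibroblast-like nuclei (-0.18, 8 of 10 lower). Mitochondrial biogenesis genes were in the lowest 2.5% in myeloid-like nuclei (-0.41, 4 of 6 measured members lower), and no list of 25 measured was in mural-like nuclei. The endothelial list left the highest 2.5% with random lists matched also on length, at start sites, with 3000 fragments required, without the 5% of nuclei with most fragments and with fragments shorter than a nucleosome. The fibroblast list left the lowest 2.5% with 3000 fragments required (-0.11) and with fragments shorter than a nucleosome (-0.12). It also left with the fibroblast-like cluster taken at resolution 1.5 (-0.18). That cluster held 315 nuclei under sunitinib and 382 under vehicle, against 301 and 381 before, so removal of low-quality nuclei was not tested there. In endothelial-like nuclei thinned to equal numbers of fragments 1 list lay in the lowest and 4 in the highest 2.5%. In fibroblast-like nuclei without the 5% with most fragments these numbers were 4 and 1. With nuclei thinned to equal numbers of fragments the fibroblast list stood at 0.17 and the endothelial list at 0.05, and without the 5% of nuclei with most fragments the myeloid list stood at 0.13.

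The second comparison, sunitinib plus Yoda1 against sunitinib, asks what the PIEZO1 activator added in hearts under the inhibitor. Fragments over heart muscle genes were more frequent with Yoda1: the 10 cardiomyocyte markers summed to 2.02 times their level in the sunitinib library (interval 1.81 to 2.24), with all 10 higher and the intervals of 6 above 0. Ryr2, the calcium release channel, stood at a log2 ratio of 1.19 (0.94 to 1.43), Rbm20, the splicing factor of titin, at 1.19 (0.85 to 1.5), the sodium-calcium exchanger gene Slc8a1 at 1.14 (0.76 to 1.47), the neuregulin receptor gene Erbb4 at 1.11 (0.75 to 1.43), Fhod3, a sarcomere formin, at 0.92 (0.58 to 1.22), and Ttn at 0.87 (0.52 to 1.18). Palld (1.14), the laminin gene Lama2 (1.00), Synpo (0.95), Kif13a (0.87) and Setbp1 (0.87) were also among the 12 highest. The lowest ratios included Arpp21, a member of the immature thymocyte list, at -1.86 (-3.16 to -0.97). Among them were also Runx1 at -1.37 (-2.09 to -0.79), Tox at -1.35 (-2.36 to -0.60), Dock2 at -1.06 (-1.81 to -0.46) and the clock gene Arntl at -0.98 (-1.84 to -0.33). The median of the 821 measured genes was 0.03.

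Of the 27 lists, 8 lay in the highest 2.5% of matched random lists with Yoda1 added, and 0 in the lowest. Their medians were 0.86 for the fetal and stress programme (12 of 14 higher), 0.84 for calcium handling (13 of 14), 0.69 for sarcomere genes (16 of 18), 0.50 for fatty acid oxidation (15 of 18), 0.49 for extracellular matrix genes (11 of 15), 0.46 for cardiac ion channels (12 of 15), 0.37 for mitochondrial biogenesis (10 of 15) and 0.28 for oxidative phosphorylation (13 of 18). Ppargc1a stood at 1.26 (0.55 to 1.84; 22 fragments) and Flnc at 1.01 (0.21 to 1.64; 18 fragments), and relative to the summed cardiomyocyte markers at 0.25 (-0.46 to 0.83) and 0.00 (-0.80 to 0.63). The 12 lowest genes of the cardiomyocyte-like nuclei stood at -0.44 (-0.65 to -0.25) when summed and set against those markers, with Bcl9 at -1.02, Rfx4 at -1.23 and Mafk at -1.60. Piezo1 stood at 0.48 (0.00 to 0.90; 43 fragments) and at -0.53 (-1.01 to -0.11) relative to those markers. Whole libraries also hold the other cell classes. In the sunitinib library Piezo1 took 841 of 4141915 fragments in vascular endothelial-like nuclei and a smaller part, 169 of 2029762, in cardiomyocyte-like nuclei. Relative to the cardiomyocyte markers, Piezo1 and the 12 summed genes therefore cannot tell lower accessibility from a larger share of cardiomyocyte chromatin. Markers of the lymphoid classes stood at 0.682 times the sunitinib level (0.566 to 0.808), those of vascular endothelium at 0.951 (0.808 to 1.11), of fibroblasts at 0.875 (0.653 to 1.13), of epicardium at 0.518 (0.280 to 0.829) and of lymphatic endothelium at 1.35 (1.03 to 1.72). Of the 12 nuclei called with Yoda1, 7 were cardiomyocyte-like, 2 endothelial-like, 2 endocardial-like and 1 mural-like. T-like nuclei numbered 0, which allows a share of up to 25%. These nuclei were called from all fragments, and their classes depended on the processing. At resolution 1.5, 4 were cardiomyocyte-like and 3 unnamed. With nuclei thinned to 1000 fragments, 1 was cardiomyocyte-like and 9 were unnamed. Without the 5% of nuclei with most fragments, 9 of 11 were cardiomyocyte-like. The 7 cardiomyocyte-like nuclei held 9950 fragments, too few for any gene to reach the minimum, so cardiomyocytes could not be compared apart from other cells.

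**Figure D5:**
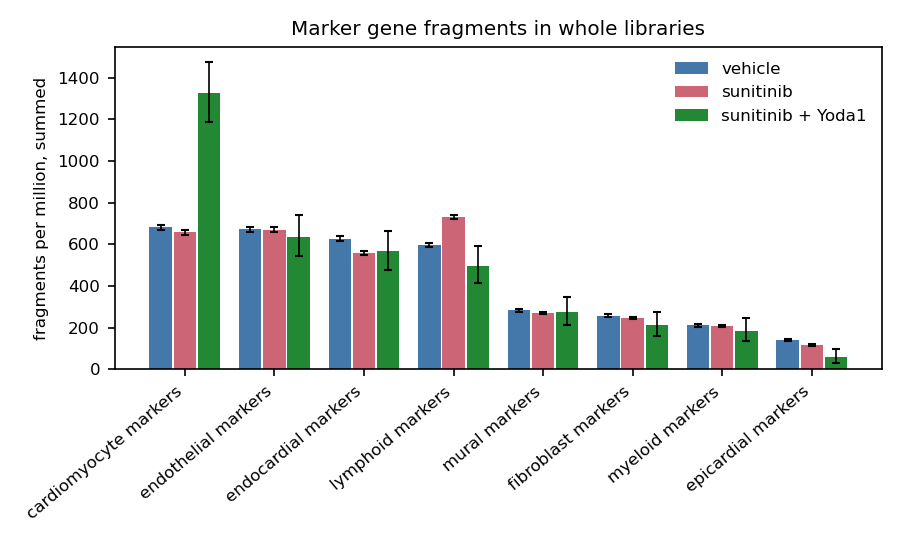
Summed cell type markers, in fragments per 1000000, in the whole vehicle, sunitinib and sunitinib plus Yoda1 libraries, the last with fragments of at least 100 read pairs, with 95% counting intervals. Cardiomyocyte markers stand at 683 under vehicle, 657 under sunitinib and 1325 under sunitinib plus Yoda1.

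The third comparison, sunitinib plus Yoda1 against vehicle, asks how far the combined treatment stood from the untreated heart. Muscle genes again led, with Ryr2 at 1.17 (0.92 to 1.40), Rbm20 at 1.09 (0.75 to 1.40), Slc8a1 at 0.98 (0.60 to 1.31), Rcan2, a regulator of calcineurin, at 0.88 (0.46 to 1.25), Erbb4 at 0.87 (0.51 to 1.19) and Zfpm2, a partner of GATA factors in the heart, at 0.80 (0.38 to 1.17). The summed cardiomyocyte markers stood at 1.94 times the vehicle level (1.74 to 2.16). Lists in the highest 2.5% were calcium handling (0.82), sarcomere (0.69), fatty acid oxidation (0.62), the fetal and stress programme (0.51) and oxidative phosphorylation (0.43), and the kinases that sunitinib blocks were the 1 list in the lowest 2.5% (-0.45, 8 of 9 lower; -0.08 within 1 kb of transcription start sites). Of these kinases 7 had 3 to 12 fragments with Yoda1. The list left the lowest 2.5% with all fragments (-0.06), with at least 10 read pairs (-0.05) and with 1 fragment per start and end (-0.24). Flt1 stood at -0.60 (-1.20 to -0.10), Kdr at 0.43 (-0.23 to 0.97), Piezo1 at 0.46 (-0.03 to 0.88) and Ppargc1a at 0.60 (-0.12 to 1.17). The lowest genes of the 787 measured were Glis1 (-1.68, -2.89 to -0.83), the glutamate receptor gene Grik4 (-1.28) and Megf6 (-1.20). With all fragments in place of those with at least 100 read pairs, Flt1 stood at 1.10 and 8 lists were in the highest 2.5%.

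Promoters took 16.2% of fragments under vehicle, 19.2% under sunitinib and 16% under sunitinib plus Yoda1, and 22.5%, 23.2% and 16.6% in called nuclei. Genes that were lower under sunitinib tended to be higher with Yoda1: across 821 genes, which are not independent replicates, the correlation between the first and second comparisons was -0.49, where libraries simulated without differences gave a mean of -0.07 (range of 95%, -0.17 to 0.01) from the shared sunitinib library alone. The T lymphocyte genes, high under sunitinib and low with Yoda1, took part in this: without nuclei of the lymphoid classes the correlation was -0.15 (simulated -0.08, -0.19 to 0.01), and with the other libraries read only from barcodes under 500 fragments it was -0.006 (simulated -0.12, -0.20 to -0.02).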

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

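Tests of explanations in this part were chosen after the result was seen, except those with thinned nuclei and without the nuclei with most fragments, which were planned. The bound for the thinned nuclei was set afterwards.

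Among barcodes with under 500 fragments, which the class comparisons do not use, genes of immature thymocytes carried 340.3 fragments per 1000000 in the sunitinib library and 202.2 in the vehicle library. In the sunitinib plus Yoda1 library, fragments with fewer than 100 read pairs, which the whole-library comparisons left out, piled up in single windows of 1 kb. The window at Flt1 (chromosome 5, 147611001 to 147612000) held 157 of them, where all fragments numbered 6 under vehicle and 7 under sunitinib. The window at Chl1 (chromosome 6, 103649001 to 103650000) held 536, against 186 and 254, and also 149 with at least 100 read pairs, which were kept. The window at Greb1 (chromosome 12, 16747001 to 16748000) held 70, against 4 and 5.

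The larger share of T lymphocyte-like nuclei under sunitinib was not removed by equal depth: with each nucleus thinned to 1000 fragments the share was still 3.51 times that of vehicle. Mature T cells of the blood are argued against, since genes of immature thymocytes (among them Rag1, Rag2, Dntt, Ptcra, Arpp21, Cd8b1 and Themis) stood above those of mature T cells by 2.59 in median log2 ratio. Thymus tissue carried along with the heart is a candidate explanation, since in T-like nuclei the immature genes stood above their level in non-lymphoid nuclei by a median of 2.93 in the sunitinib library and 3.18 in the vehicle library. The 3 of these genes not seen before the list was written gave 2.40 and 2.59, mature T cell genes 0.34 and 0.72, genes of all T cells 2.37 and 2.41, and genes of thymic epithelium 0.23 and 0.88. An effect of sunitinib on T cells within the heart stays open and was not tested.

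The lower accessibility of heart muscle and metabolic gene lists in cardiomyocyte-like nuclei under sunitinib goes in part with nuclei of low quality. Without these nuclei the median of the 11 lists in the lowest 2.5% moved from -0.303 to -0.169, or 55.7% of its former size, too near the 50% set as the bound, so for the lists as a set low quality and sunitinib cannot be told apart. The fetal and stress programme stayed at percentile 0.04 of matched random lists without them, which argues against low quality as its whole cause. Without the 5% of nuclei with most fragments that list was at percentile 4.87, inside the range of 95% of random lists, so a few very deep nuclei, among which doublets were not removed, may carry much of its difference. A response of cardiomyocytes to sunitinib stays open, untested without further animals.

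The higher level of heart muscle gene fragments with Yoda1 was not removed by the filter on read pairs, under which cardiomyocyte markers stood at 2.02 times the sunitinib level. A larger share of cardiomyocyte chromatin in that library may account for it. Markers of lymphatic endothelium also stood at 1.35 times that level. Their median log2 ratio over the other nuclei was 0.14 in the cardiomyocyte-like and -1.30 in the T-like cluster. A shift between these classes could thus raise them too, so their rise cannot decide and the explanation stays open. Ppargc1a stood at 0.25 relative to the cardiomyocyte markers, with an interval on both sides of 0, so a change of its own beyond the cardiomyocyte content cannot be told apart from none at 22 fragments. Yoda1, the low yield of the library and its pipeline version came together in the same library, and an effect of Yoda1 on the heart was not tested. With 583792 unique fragments from 209296546 read pairs and 12 called nuclei, a failed or wrongly assigned library also stays open, and it would change the meaning of each value of this group.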

How the results depend on the processing

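Alternatives that leave out the lymphoid or low-quality nuclei, or use other read-pair minimums, 1 fragment per start and end, or barcodes under 500 fragments, were chosen after the data were seen. The planned motif comparisons were not run, for want of a genome sequence. Few unique fragments limit the comparisons with the sunitinib plus Yoda1 library, where 821 and 787 genes were measured, against 15466 between the other whole libraries. Of the values of named genes under all alternatives, 250 in cardiomyocyte-like nuclei moved by less than their intervals, 53 by more and 2 whose interval had excluded 0 changed sign, and in whole libraries these numbers were 818, 95 and 5. The 818 include values that could not move. For sunitinib against vehicle these were 34 with all fragments and 34 with at least 10 read pairs. The read-pair minimum was set only for the sunitinib plus Yoda1 library. Genes whose interval included 0 are not counted for their sign. For all values below, the cause was not tested.

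With 3000 fragments required, nuclei numbered 805 (vehicle), 1400 (sunitinib) and 1 (sunitinib plus Yoda1), cardiomyocyte-like shares were 11.2% and 10.8%, and T-like shares 5.34% and 27.1% (vehicle, sunitinib). With 500 required, vehicle gave 4142 nuclei and sunitinib plus Yoda1 25. At resolution 1.5 cardiomyocyte-like shares were 10.3% and 10.2% and T-like shares 8.55% and 34.0%, at resolution 0.4 the T-like share under sunitinib was 38.9%, and with nuclei thinned to 1000 fragments cardiomyocyte-like shares were 9.44% and 8.91%.

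In cardiomyocyte-like nuclei, sunitinib against vehicle, 11 of 27 lists were in the lowest 2.5%. This number was 6 with random lists matched also on length, 0 of 19 within 1 kb of start sites, 1 without the 5% of nuclei with most fragments, 7 over all called nuclei, 1 of 19 with equal fragments per nucleus (and 2 in the highest 2.5%), 5 of 26 with fragments shorter than a nucleosome and 2 of 26 without low-quality nuclei. Medians that changed sign or left the outer range near 0 were sarcomere (0.043 without the deepest nuclei, -0.019 without low-quality nuclei), calcium handling (0.10 at start sites), and stretch-gated channels (-0.056) and fatty acid oxidation (0.026) over all nuclei. Over all nuclei Cntnap5b stood at -0.11 and Map2 at -0.0029. Piezo1 stood at -0.31 at start sites. With equal fragments the TGF-beta list in endothelial-like nuclei stood at 0.050 and the matrix list in fibroblast-like nuclei at 0.17. Without the deepest nuclei the mitochondrial list in myeloid-like nuclei stood at 0.13.

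In whole libraries at start sites Pdgfrb stood at 0.12 and Flt3 at -0.038 (sunitinib against vehicle), Flt3 at 1.23 (sunitinib plus Yoda1 against sunitinib), and the kinase list at -0.078 (sunitinib plus Yoda1 against vehicle). In the last comparison Flt1 stood at 1.10 with all fragments and 1.00 with 1 fragment per start and end, and lists in the highest 2.5% numbered 8 with all fragments, 8 with at least 10 read pairs and 9 with 1 fragment per start and end, with 0 in the lowest 2.5% in each. Cardiomyocyte markers with Yoda1 stood at 2.38 times the sunitinib level per promoter fragment and at 1.80 without lymphoid nuclei. The correlation between comparisons was -0.24 with fragments shorter than a nucleosome (inside the simulated range of -0.30 to 0.13), -0.15 without lymphoid nuclei (inside -0.19 to 0.01) and -0.0056 with barcodes under 500 fragments (above -0.20 to -0.02).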

Other observations

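Genes in this part were named by the rule of the report applied to the other classes, which was chosen after the data were seen, as was the test of a chromosome segment.

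In vascular endothelial-like nuclei the highest log2 ratios of sunitinib to vehicle included Ect2, a guanine nucleotide exchange factor needed for cytokinesis (0.74, 0.33 to 1.18), and Lfng, the Fringe enzyme that tunes Notch receptors (0.67, 0.35 to 1.01), and the lowest included Plekhb1 (-0.74, -1.13 to -0.35), the neuronal nitric oxide synthase gene Nos1 (-0.64, -0.99 to -0.31) and Edil3, a matrix ligand of integrins (-0.60, -0.96 to -0.25). In fibroblast-like nuclei the fibrillar collagen gene Col5a3 was lowest (-0.85, -1.24 to -0.47), with Timp3, an inhibitor of matrix metalloproteinases (-0.52, -0.84 to -0.20), Skil, a repressor of TGF-beta signalling (-0.50, -0.91 to -0.09), and Aldh1a1, an enzyme of retinoic acid synthesis (-0.49, -0.86 to -0.13). Prkcb (0.61, 0.20 to 1.04) and Bach1, a repressor of haem-responsive genes (0.58, 0.16 to 1.01), were among the highest there.

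In endocardial-like nuclei the von Willebrand factor gene Vwf (0.50, 0.09 to 0.90), the basement membrane gene Col4a2 (0.61, 0.21 to 1.00) and the tight junction gene Tjp1 (0.56, 0.15 to 0.95) were among the highest, and Smad6, an inhibitor of BMP signalling, was among the lowest (-0.55, -1.02 to -0.12). In mural-like nuclei Ptprd (-0.87, -1.28 to -0.48) and Ski, a repressor of SMAD signalling (-0.53, -0.93 to -0.15), were lowest and the focal adhesion kinase gene Ptk2 (0.48, 0.07 to 0.89) was among the highest. In myeloid-like nuclei the Src family kinase gene Lyn (0.49, 0.14 to 0.86) and the TGF-beta receptor gene Tgfbr2 (0.49, 0.10 to 0.88) were highest and the transcription factor gene Tcf12 lowest (-0.50, -0.94 to -0.08). In T-like nuclei the mitophagy kinase gene Pink1 (1.02, 0.35 to 1.87) and Cd3g (0.87, 0.27 to 1.60) were among the highest and Adam12 was lowest (-0.86, -1.28 to -0.40). Vwf and Cd3g were among the markers that named the endocardial- and T-like classes, so their ratios and these classes are not independent.

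Sept10, the highest gene in cardiomyocyte-like nuclei, Sowahc, among the highest in endothelial-like nuclei (0.63, 0.34 to 0.94), and P4ha1, the highest in fibroblast-like nuclei (0.66, 0.27 to 1.07), lie side by side on chromosome 10. Contiguous windows of 20 kb with a whole-library log2 ratio above 0.1 spanned 59120001 to 59360000, 240 kb that hold Sept10 and Sowahc and end within P4ha1. Relative to flanks of the same length the segment stood at 0.72 (0.63 to 0.81) in the whole libraries, at 0.60 (0.46 to 0.75) in barcodes under 500 fragments, at 0.74 (0.53 to 0.96) in vascular endothelial-like nuclei, at 0.84 (0.51 to 1.17) in fibroblast-like nuclei and at 0.62 (0.23 to 1.00) in cardiomyocyte-like nuclei. The edges were set on these same libraries and the classes named here brought the segment up, so these values are no test. With the edges set only in barcodes under 500 fragments (59120001 to 59380000), the 6 other classes stood at 0.50 when pooled (0.27 to 0.73), from 0.12 (-0.42 to 0.66) in endocardial-like to 1.09 (0.42 to 1.76) in myeloid-like nuclei, where 3 copies against 2 would give 0.58. A difference in copy number between the animals may therefore lie behind these genes, as a hypothesis. In the sunitinib plus Yoda1 library the first segment stood at -1.16 (-1.62 to -0.71) to sunitinib, beyond what 2 copies against 3 would give. To vehicle it stood at -0.43 (-0.89 to 0.02). These values used all fragments of that library, without the minimum of read pairs set for the other whole-library comparisons. They therefore cannot decide whether 1 extra copy under sunitinib accounts for that library. Of 119300 overlapping segments of that length, 99 stood as far from their flanks, in 34 separate places, so such steps also occur elsewhere and other causes stay open.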
